A study of Mus musculus with 12 samples.

How the data were processed

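Gene expression was measured in the spinal cord and skeletal muscle of male AR-97Q mice, which carry a human androgen receptor with an expanded glutamine tract and model spinal and bulbar muscular atrophy. Mice were untreated or received pioglitazone, an agonist of the nuclear receptor PPAR gamma, mixed into the diet at 0.02% starting at week 6, and tissue was taken at week 13. Per the labels, RNA came from 3 mice of each group, and 0.6 µg of each RNA was labelled with Cy3. There were 12 one-colour arrays of Agilent design 028005, 3 in each of 4 groups. Samples were grouped by tissue and treatment and numbered 1 to 3 from their titles. The labels do not say whether equal numbers in both tissues are 1 mouse.

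The authors scanned the arrays and quantified them with Agilent Feature Extraction 10.10.1.1 under protocol GE1_1010_Sep10. Per the file headers, the processed signal is an intensity, corrected for background and spatial trend within each array and not normalised between arrays. The raw median signal and the local background median are, per the file headers, intensities too. The deposited flags are of another kind than intensities: they are 0 or 1 marks for spots well above background, saturated or unlike their replicates, and a code for control spots. The deposited series matrix holds linear intensity values, the processed signal of each spot times 1 factor per array, as the values themselves showed. It is neither log-transformed nor centred, holds no ratio, and its scaling target is not stated. Its medians, in the order of replicates 1, 2 and 3, were 93.1, 84.8 and 84.8 in untreated cord, 87.9, 82.4 and 82.8 in pioglitazone cord, 54.2, 62.7 and 54.5 in untreated muscle, and 59.1, 55.5 and 60.5 in pioglitazone muscle.

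Of 62976 spots, 3671 were controls and were left out, as were spots with an outlier flag. The main value was log2 of the processed signal minus the array's 75th percentile of it. The spots of a probe were averaged. A probe was kept if the software called it well above background on all 3 arrays of at least 1 group compared. For the test of differences between tissues, this had to hold in at least 1 group of each tissue. A gene was represented by its kept probe of highest mean, and where several probes of a named gene disagreed in direction this is stated. The files pair probes with database accessions and not with gene symbols. RefSeq accessions were therefore matched without version to a gene table of assembly GRCm38.p6, used for names alone. Of 55681 distinct probes, 26762 received a symbol, covering 20284 genes, and the other 28919 kept the identifier in the file. Per the file headers the array was designed on genome build mm9, for which no annotation was at hand, so no gene positions are given.

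Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of adjusted p under 0.05. The 6 arrays of a tissue entered each treatment comparison, the 6 untreated arrays the tissue comparison, and all 12 the test of whether the treatment effect differed between tissues. These p-values measure spread between mice. An exact permutation test of 3 against 3 cannot give a p under 0.1, so none was used for single genes. A fold against a group in which no array measured the gene above background is written as "at least", with values under the floor raised to it. The same bound is given where only some arrays of a group measured a named gene, unless none of its values lay under the floor. Such a bound holds for the main values alone and is no limit on the error of the estimate. The floor is the lowest signal on that array that was called well above background, which lay between -4.94 and -3.90 on the log2 scale.

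Gene lists, 38 in number, were written before the data were examined, as were the tests, alternatives and naming rules. Some genes stand on more than 1 list, so calls of lists that share members are not independent. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, which compares a list with the other genes. The same test with an estimated correlation, and fry, stand beside it. Genes were named by rule. For each treatment comparison these were the 5 largest rises and 5 largest falls that passed with groups that did not overlap, and otherwise the smallest unadjusted p-values. Transcripts without a gene name were counted and not named. For each list described, up to 4 passing members were named, or the 1 or 2 of smallest p. A fixed set of 29 genes was reported in both tissues whatever its values. For the difference between tissues the 5 smallest p-values were named, and for the tissue comparison members of fibre, neuron and myelin lists.

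Alternatives covered background correction (limma's normexp with an offset of 50), normalisation (quantile, median), filters on dim probes, the probe rule, the variance model, a shared fit of 12 arrays, slide, replicate number and mouse as blocks, the series matrix values, and leaving out each array. The files have no mean signal column, so normexp used the raw medians. Comparisons within a slide, the slide block for gene lists, and leaving out untreated replicate 3 of both tissues were chosen after seeing the data. On simulated data at the size of the muscle comparison (20055 genes, 50 changed genes per fold size), the procedure recovered 22.0% of changes of 1 log2 unit, 68.0% of 2, 86.0% of 3 and 98.0% of 4. At the size of the cord comparison (21844 genes), it recovered 62.0% of changes of 1 log2 unit and 98.0% of 2. The simulated errors were independent between genes and arrays, without shifts shared by the genes of an array or slide. These shares therefore do not tell how many changes of such sizes the real comparisons would find. Tables and figures were made with Python, pandas, NumPy and matplotlib.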

Results

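Transcripts were measured on 12 one-colour arrays from AR-97Q mice, a transgenic model of spinal and bulbar muscular atrophy, a motor neuron and muscle disease caused by a lengthened glutamine tract in the androgen receptor. Spinal cord and skeletal muscle were each sampled in 3 untreated mice and 3 mice fed pioglitazone, a drug that activates PPAR gamma. The number of arrays limits the precision. All 6 cord arrays shared a slide with muscle of untreated replicates 1 and 2, while muscle of untreated replicate 3 lay on a second slide with the 3 pioglitazone muscle arrays. In muscle, treatment and slide were thus partly aligned, and without untreated replicate 3 they coincided. Muscle values without that array cannot be told from a slide difference. Changes are log2 differences, pioglitazone minus untreated, with standard errors and 3 arrays per group throughout.

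The first question was what pioglitazone changed in skeletal muscle. Tenomodulin (Tnmd), a tendon and connective tissue protein, rose at least 12.1-fold (limma adjusted p = 0.0393), as no untreated array measured it above background. Under the alternatives its log2 difference lay between 1.51 and 4.13. Cldn5, the tight junction protein of endothelium, rose by 2.18 ± 0.17 (adjusted p = 0.0373). Lgals3, the lectin galectin-3 of macrophages and injured fibres, fell by 2.52 ± 0.25 (adjusted p = 0.0393). Prune2 fell by 2.66 ± 0.18 (adjusted p = 0.0373), and its 3 detected probes fell by 2.37 to 2.66. In limma, 20 of 20055 genes passed, 12 higher and 8 lower, and 5056 had an unadjusted p under 0.05.

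Among the other named genes that passed, C1qtnf3, a secreted adipokine-like protein, rose at least 4.54-fold, with 2 of 3 untreated arrays above background. Gzma, a protease of cytotoxic lymphocytes, rose by 2.14 ± 0.21. Ttbk1, a tau kinase, rose at least 2.90-fold, as no untreated array measured it above background. Muc15, a membrane mucin, fell at least 1.91-fold to below background on all pioglitazone arrays. Marveld2, a protein of tricellular junctions, fell by 1.65 ± 0.18, and Gstm2, a glutathione transferase, fell by 1.47 ± 0.14. Adjusted p-values of these 6 genes lay between 0.0373 and 0.0441. The groups did not overlap for any of the 10 genes because the naming rule required it. The groups did not overlap for 6853 genes, 34.2% of those tested. Chance gives 10% for a gene kept without regard to groups. The filter kept dim genes measured in a single group, and treatment was partly aligned with slide, so 10% is only a rough guide. The count of 20 was not stable when 1 array was left out, which leaves a group of 2. It was 263 without untreated replicate 1, and 89 without untreated replicate 3, where treatment and slide coincide. It was 0 without untreated replicate 2 or without pioglitazone replicate 1, 2 or 3. With slide as a block 4482 genes passed, and within the second slide 3314 did. Both counts set the pioglitazone arrays against the same single untreated array, replicate 3, which stood apart, so neither is separate evidence for the 20. Under the other alternatives the count lay between 0, without a filter on dim probes or with replicate number as a block, and 3479, in a shared fit of 12 arrays. Sizes moved as well. Over all alternatives the log2 difference ran from 0.69 to 3.95 for Ttbk1, 0.76 to 2.36 for C1qtnf3 and 0.78 to 2.51 for Gzma. It ran from -3.00 to -0.23 for Muc15, -1.83 to -0.63 for Marveld2 and -2.78 to -1.22 for Prune2. Cldn5 (2.02 to 2.38), Lgals3 (-2.93 to -2.32) and Gstm2 (-1.54 to -1.38) moved less. The fold bounds of Tnmd, Ttbk1, C1qtnf3 and Muc15 were thus not reached under every alternative.

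**Figure D1:**
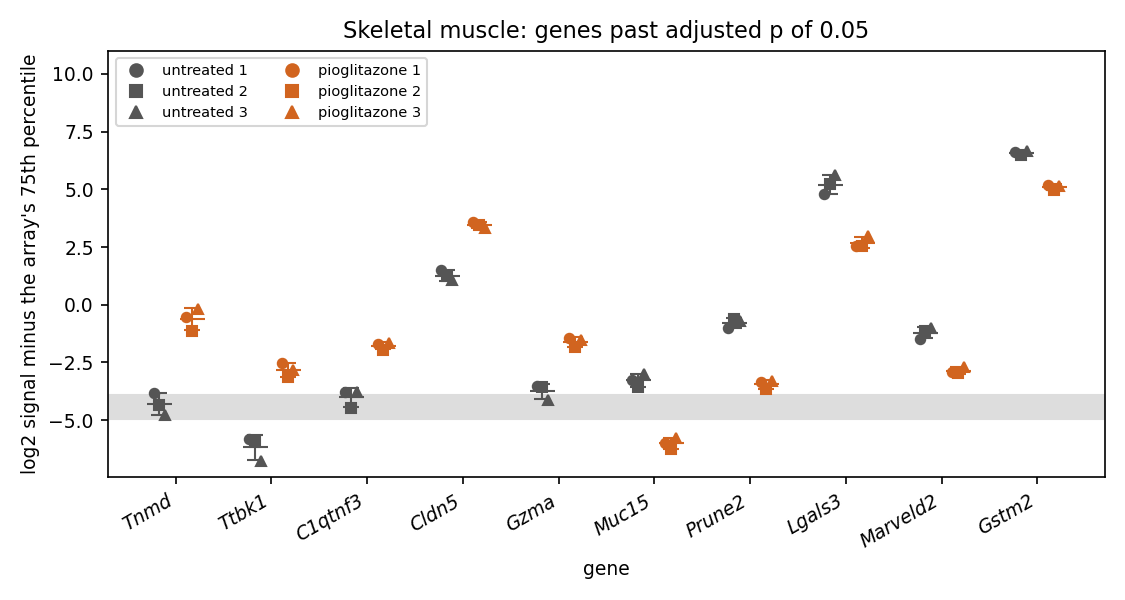
Signal of the 10 named muscle genes on each array, as log2 of the processed signal minus the array's 75th percentile, with group mean and SD (n = 3). The grey band spans the detection floors of the arrays, and for each gene the groups lie apart, as the naming rule required.

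Connective tissue and vessel genes rose as groups in muscle. Extracellular matrix genes rose by a median of 1.46, with 22 of 23 members higher (camera adjusted p = 8.97e-12; adjusted p = 0.345 with an estimated correlation). No member passed over all genes, and 17 did when adjusted over the list alone. Sparc, which binds collagen, was higher by 1.49 ± 0.20 and the basement membrane collagen Col4a2 by 1.28 ± 0.18 (adjusted p = 0.0548 and 0.0565). Fibroblast markers rose by a median of 1.22 (adjusted p = 0.000465; adjusted p = 0.412 with an estimated correlation), with 0 members passing over all genes and 8 higher and 1 lower when adjusted over the list alone. This list shares Col1a1, Col1a2, Col3a1, Dcn and Lum with the extracellular matrix list, so their rises are not separate evidence. The growth factor binding protein Igfbp2 was higher by 2.23 ± 0.32, with 2 of 3 untreated arrays above background. The fibrillar collagen Col1a1 was higher by 4.56 ± 0.82 (limma adjusted p = 0.0565 for Igfbp2 and 0.0754 for Col1a1). Endothelial markers rose by 0.66 (adjusted p = 4.92e-06; adjusted p = 0.412 with an estimated correlation), with Cldn5 passing over all genes and 6 members adjusted over the list alone. The fibroblast median was 0.53 with normexp and 0.52 with probes above background on all arrays. Without untreated replicate 3 the medians of these 3 lists were 1.20, 0.83 and 0.53, and within the second slide, as with slide as a block, 1.72, 1.96 and 1.06. As for the genes, each slide value in muscle rests on untreated replicate 3 alone. The values without that array compare slides as well as treatments.

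Macrophage genes rose as well. Microglia and macrophage markers rose by a median of 1.09 (adjusted p = 6.66e-07; adjusted p = 0.345 with an estimated correlation), and 12 of 17 members passed when adjusted over the list alone against 0 over all genes. The leukocyte phosphatase Ptprc was higher by 1.21 ± 0.23 and the myeloid adaptor Tyrobp by 1.47 ± 0.28. Genes of NADPH oxidase, the phagocyte enzyme that makes superoxide, rose by 0.60 (adjusted p = 0.00224; adjusted p = 0.345 with an estimated correlation), with the subunit Ncf4 higher by 2.04 ± 0.29. Classical and alternative activation genes of macrophages rose by 0.75 and 0.84 (adjusted p = 0.00224 and 0.01; adjusted p = 0.345 with an estimated correlation for both). The interferon regulatory factor Irf5 was higher by 1.18 ± 0.16. Members of the alternative list went both ways, as Retnla, made by alternatively activated macrophages, was higher by 3.22 ± 0.57 and the chitinase-like Chil3 at least 4-fold lower, with 1 of 3 pioglitazone arrays above background (adjusted p = 0.0729 and 0.0547). The macrophage median was 0.92 without untreated replicate 3 and 1.44 within the second slide and with slide as a block. With normexp the oxidase, classical and alternative medians were 0.34, 0.45 and 0.35. Within that slide camera no longer called the classical and alternative lists, at 0.83 and 0.93. Blood cell markers were at a median of 1.06 in the same samples, with 8 of 11 members higher and no call (adjusted p = 0.277). They were at 0.39 without untreated replicate 2, where they lay at -2.68 against the other muscle arrays, and at 0.37 within the second slide and with slide as a block. The globin Hbb-bt was at 1.94 and the neutrophil protein S100a8 at -2.45 (adjusted p = 0.230 and 0.0754). Over the oxidase, classical and alternative lists, 4, 4 and 3 members passed when adjusted over the list alone, and none over all genes.

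Lists of fast fibre, oxidative phosphorylation, glycolysis and PPAR target genes were also higher. Fast fibre genes rose by 0.52, in 16 of 16 members (adjusted p = 0.000382; adjusted p = 0.589 with an estimated correlation), and the Z-disc protein Myoz3 was higher by 1.72 ± 0.44. Oxidative phosphorylation genes rose by 0.23 in 33 of 34 members (adjusted p = 0.000547; adjusted p = 0.670 with an estimated correlation), but by 0.06 without untreated replicate 3, when camera no longer called them, and by 0.35 without untreated replicate 1. Glycolysis genes rose by 0.46 (adjusted p = 0.00695; adjusted p = 0.589 with an estimated correlation), and by 0.25 without untreated replicate 3. In the main comparison camera did not call fatty acid oxidation or slow fibre genes. Under 16 alternatives the fatty acid oxidation median lay between -0.20 and 0.06 and the slow fibre median between 0.19 and 0.54. Target genes of PPAR in lipid handling rose by 0.54, with 19 of 31 members higher (adjusted p = 0.0200; adjusted p = 0.592 with an estimated correlation), but camera did not call them without untreated replicate 2, pioglitazone replicate 1 or pioglitazone replicate 2, at 0.32, 0.56 and 0.25, or without a filter on dim probes, at 0.52, and they were at 0.96 without pioglitazone replicate 3. Adipocyte markers were at a median of 0.83 in the same samples, with 11 of 14 members higher and no call (adjusted p = 0.0735, and 0.000235 to 0.670 under the alternatives), and at -0.20 without untreated replicate 3, where they lay at -2.34 against the other muscle arrays. The adipocyte list shares Adipoq, Plin1, Cidec and Fabp4 with the PPAR targets. Of the PPAR targets, the glycerol channel Aqp7 was higher by 2.50 ± 0.63, with 2 of 3 untreated arrays above background. The lipid droplet protein Plin2 was higher by 1.26 ± 0.40 (limma adjusted p = 0.102 for Aqp7 and 0.131 for Plin2). Medians of the fast fibre, oxidative phosphorylation, glycolysis and PPAR lists were 0.79, 0.47, 0.65 and 0.24 within the second slide, and with slide as a block the same except for 0.60 in the PPAR list. In each of these 4 lists, 0 members passed over all genes and 0 adjusted over the list alone.

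Interferon response genes rose by 0.84 (adjusted p = 0.00104; adjusted p = 0.589 with an estimated correlation), with the guanylate binding protein Gbp2 higher by 1.44 ± 0.31. Immediate early genes rose by 0.70 (adjusted p = 0.000547; adjusted p = 0.412 with an estimated correlation) and Schwann cell markers by 0.35 (adjusted p = 0.0244; adjusted p = 0.589 with an estimated correlation). Without untreated replicate 3 the interferon median was 0.55, and camera did not call the Schwann list without pioglitazone replicate 2 or 3, at 0.33 and 0.36, without a filter on dim probes or with probes above background on all arrays, at 0.35 in both cases. The Schwann median was 0.57 without pioglitazone replicate 1, and the immediate early median was 0.35 with normexp. Ribosomal protein genes fell by 0.31 in 24 of 25 members (adjusted p = 3.41e-05; adjusted p = 0.473 with an estimated correlation). Proteasome subunits fell by 0.19 (adjusted p = 0.00811) and unfolded protein response genes fell by 0.31 (adjusted p = 0.0320), both with adjusted p = 0.589 with an estimated correlation. The endoplasmic reticulum chaperone Hspa5 was at -1.01 ± 0.29 (adjusted p = 0.114), and its list was no longer called without untreated replicate 1, untreated replicate 3 or pioglitazone replicate 3, at -0.31, -0.24 and -0.33. The proteasome median was -0.30 without untreated replicate 2 and -0.33 without pioglitazone replicate 2, and -0.12 with series matrix values. Within the second slide the interferon, immediate early and Schwann medians were 1.42, 1.15 and 0.57 and the ribosomal, proteasome and unfolded protein medians -0.27, -0.35 and -0.58. Adjusted over the list alone, 0, 4 and 2 members of the former 3 lists and 6, 0 and 0 of the latter 3 passed, and none over all genes. Camera called 17 of 38 lists in muscle, fry 8, and camera with an estimated correlation 0, where 5 had an unadjusted p under 0.05. Chance splits of the same arrays gave up to 15 lists.

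Genes of denervated muscle had a median of -0.65, which camera did not call (adjusted p = 0.0973) and fry did (adjusted p = 0.0495), as did camera without pioglitazone replicate 3, at -0.78, with normexp, at -0.52, without a filter on dim probes, at -0.61, with probes above background on all arrays, at -0.68, and with replicate number as a block, at -0.65. The adhesion molecule Ncam1 was at -1.77 ± 0.27 (adjusted p = 0.0618), and its 3 probes ranged from -1.77 to -0.85. Genes fixed in advance stayed short of the threshold in muscle. The fatty acid transporter Cd36 was at 0.83 ± 0.26, the fatty acid binding protein Fabp4 at 1.88 ± 0.68, the uncoupling proteins Ucp2 and Ucp3 at 1.13 ± 0.40 and 1.13 ± 0.68, and the lipase inhibitor Angptl4 at 1.31 ± 0.65, with adjusted p-values from 0.133 to 0.331. Pdk4, Fabp3, Cpt1b, Pparg and Ppargc1a were at 0.99, 0.54, -0.08, -0.10 and -0.26. Ar was at -0.06 ± 0.25, and whether its mouse probe also detects the human transgene is unknown. The microglial protein Aif1 was at 2.48 ± 0.89 (adjusted p = 0.160), Nos2 at 0.75 ± 0.21 and Itgam at -0.24, with probes that disagreed from -0.24 to 0.42. Nfkb1, whose 2 probes disagreed in direction, Hmox1, Cat and Sod2 lay between -0.12 and 0.28, and Chrng, Myog, Trim63 and Fbxo32, genes of denervation and atrophy, at -0.47, 0.72, 0.33 and -0.42. Il6, Tnf, Arg1, Gfap and Chat were not well above background.

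The second question was what pioglitazone changed in the spinal cord. Ucn, a peptide of the corticotropin-releasing factor family made in motor neurons, had the largest of the 10 named differences, -2.67 ± 0.34. Cyp26b1, which degrades retinoic acid, was at -1.48 ± 0.21 and the clock gene Per2 at -0.82 ± 0.12. Clec3b, a plasminogen binding protein, was at 1.42 ± 0.20, the mitotic protein Prc1 at 1.01 ± 0.14 and Egr2, a transcription factor of myelinating Schwann cells, at 0.85 ± 0.09. None of these passed in limma (adjusted p = 0.270 for each). Of 21844 genes, limma called 0, while 3113 had an unadjusted p under 0.05, 1560 higher and 1553 lower.

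The growth factor Tgfb3 and the ubiquitin ligase Rnf122 were at 0.78 and 0.80, and Lbx1, a transcription factor of dorsal interneurons, at -0.76. Sufu, a brake on hedgehog signalling, was at least 1.73-fold lower, with all pioglitazone arrays below background. Groups did not overlap for 5291 genes, or 24.2%, where 10% by chance is again only a rough guide under this filter. Without untreated replicate 2, and again without untreated replicate 3, 2 genes passed, and 0 when any other cord array was left out. Ar was at -0.52 ± 0.11 with groups that did not overlap (adjusted p = 0.336), and the peroxide-degrading enzyme Cat at 0.47 ± 0.10 (adjusted p = 0.336). Itgam, Aif1 and Chil3 were at 0.31, 1.1 and -1.23, with adjusted p-values of 0.336, 0.396 and 0.336. Pparg, Ppargc1a, Pdk4, Angptl4, Ucp2, Ucp3, Fabp3, Fabp4, Cpt1b, Nfkb1, Hmox1, Sod2, Gfap, Nos2, Chat and Fbxo32 lay between -0.20 and 0.19, with probes of Cpt1b and Gfap that disagreed in direction, and Plin2 at 0.35 ± 0.21. Cd36, Il6, Tnf, Arg1, Chrng, Myog and Trim63 were not well above background.

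Microglia and macrophage markers rose in cord by a median of 0.37, in 19 of 19 members (camera adjusted p = 2.80e-07; adjusted p = 0.878 with an estimated correlation). The microglial receptor Trem2 was at 0.53 ± 0.14, and 0 members passed over all genes or adjusted over the list alone. Without untreated replicate 3 the median was 0.19, still called by camera. Oligodendrocyte and myelin markers rose by 0.23 (adjusted p = 0.00645; adjusted p = 0.879 with an estimated correlation), with Gpr17, a receptor of oligodendrocyte precursors, at 2.22 ± 0.65, and the list median was 0.13 without untreated replicate 3, where the list lay at -0.42 against the other cord arrays. Schwann cell markers rose by 0.35, immediate early genes by 0.13 and heat shock genes by 0.15 (adjusted p = 0.00856, 0.0220 and 0.0220; adjusted p = 0.835, 0.862 and 0.879 with an estimated correlation). Circadian clock genes fell by 0.40 and proteasome subunits fell by 0.12 (adjusted p = 0.0128 and 0.0406; adjusted p = 0.862 and 0.928 with an estimated correlation). Without untreated replicate 3, where circadian genes lay at 0.59, their median was -0.23. Glucocorticoid response genes fell by 0.61 (adjusted p = 0.0171; adjusted p = 0.896 with an estimated correlation), and were not called without untreated replicate 3, pioglitazone replicate 1 or pioglitazone replicate 3, at -0.28, -0.39 and -0.46, while without pioglitazone replicate 2 they were at -0.98. Camera did not call the proteasome list without untreated replicate 2 or 3 or pioglitazone replicate 2 or 3, at -0.14, -0.019, -0.11 and -0.11, and it was at -0.20 without untreated replicate 1. It did not call heat shock genes without untreated replicate 2 or pioglitazone replicate 3, at 0.11 and 0.10, or immediate early genes without untreated replicate 1, at 0.12, or without a filter on dim probes, at 0.059. The latter were at 0.21 without untreated replicate 2 and 0.22 without pioglitazone replicate 2. Adjusted over the list alone, 2 Schwann genes (Egr2 and S100b), 2 immediate early genes (Egr2 and Klf2) and 2 circadian genes passed, and 0 of the other lists named here. Egr2 thus counts in both of the former lists. S100b is also on the astrocyte list and Sox10 on the oligodendrocyte list, so the Schwann rise in cord is not particular to Schwann cells.

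PPAR targets in cord had a median of -0.08 and extracellular matrix genes 0.17 (camera adjusted p = 0.856 and 0.0726). Camera called the latter in 5 of 14 alternatives: without untreated replicate 3 or pioglitazone replicate 3, without a filter on dim probes and with replicate number as a block, at 0.17 to 0.18, and with normexp, at 0.10. Without pioglitazone replicate 1 the matrix median was 0.011. The fast fibre list had a cord median of 0.67 without a call (adjusted p = 0.149), or of 1.57 with a call without untreated replicate 2, and Myh4, the myosin of the fastest fibres, was at least 8.59-fold higher, above background on 1 untreated and 3 pioglitazone cord arrays (adjusted p = 0.336). Camera called 8 of 38 lists in cord, fry 0, and camera with an estimated correlation 0, where 1 had an unadjusted p under 0.05. Other splits of the 6 cord arrays gave up to 16 lists.

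**Figure D2:**
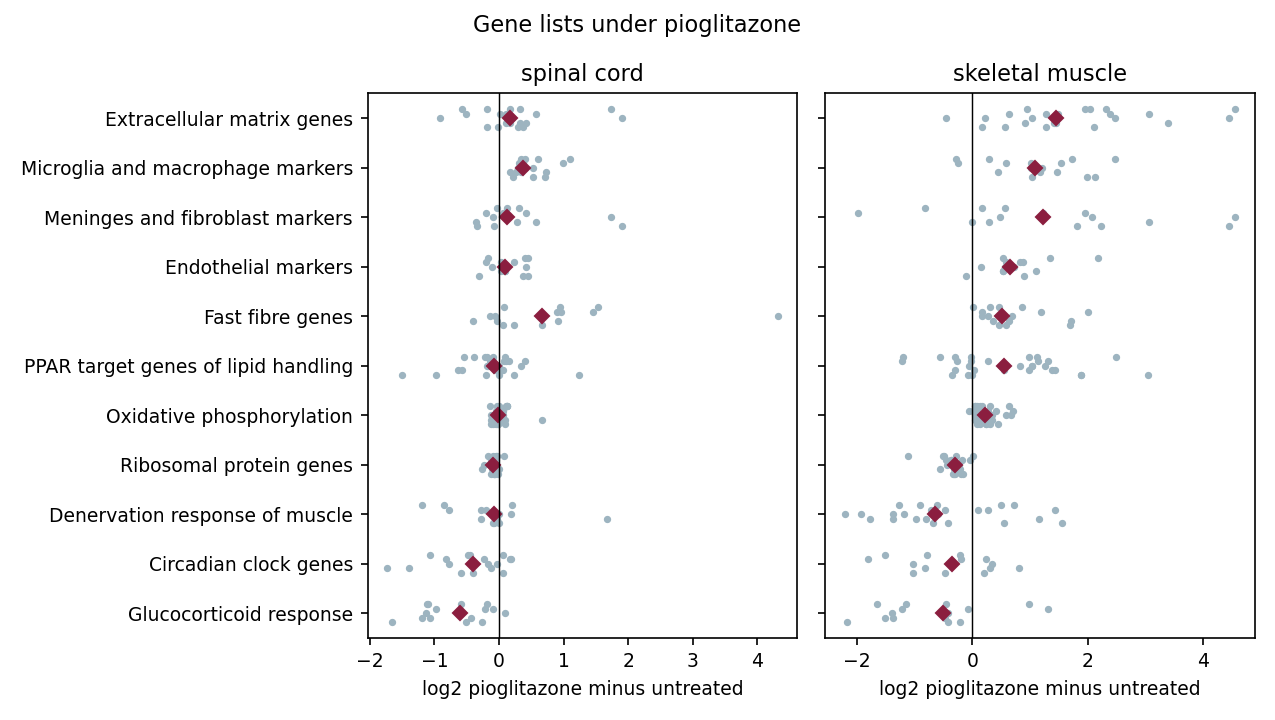
Log2 difference, pioglitazone minus untreated, of each measured member (points) of 11 gene lists in both tissues, with the list median (diamonds). The extracellular matrix median is 1.46 in muscle and 0.17 in cord, and the glucocorticoid response median is -0.50 and -0.61.

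In both tissues untreated replicate 3 stood apart from the other 5 arrays. Its mean correlation with them was 0.982 in cord, where the other arrays had at least 0.991, and 0.959 in muscle, where the others had at least 0.977. Glucocorticoid response genes were 1.22 log2 units higher on it than on the other cord arrays and 1.09 higher than on the other muscle arrays. Its macrophage genes were lower, at -0.64 in cord and -0.91 in muscle. Pioglitazone replicate 2 also had high glucocorticoid response genes, by 0.58 and 1.06, while pioglitazone replicates 1 and 3 lay between -1.41 and -0.87. Fkbp5, which feeds back on the glucocorticoid receptor, was at 2.42, 2.06 and 3.58 on untreated replicates 1, 2 and 3 in cord and at 4.71, 3.67 and 4.76 in muscle. On pioglitazone replicates 1, 2 and 3 it was at 1.09, 2.58 and 1.03 in cord and at 1.80, 4.45 and 1.95 in muscle.

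**Figure D3:**
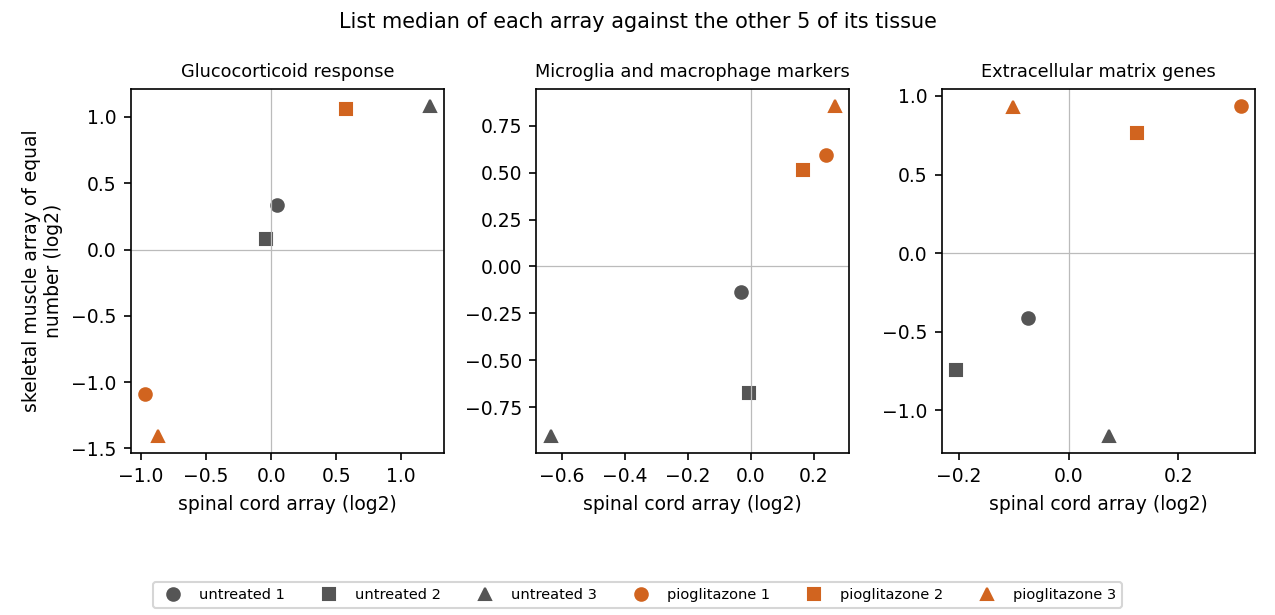
Median log2 difference of 3 gene lists on each array against the other 5 of its tissue, in spinal cord (x axis) and in the muscle array of equal number (y axis). Untreated replicate 3 and pioglitazone replicate 2 are high in glucocorticoid response genes in both tissues.

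A further comparison asked whether the effect of pioglitazone differed between the tissues. As treatment was partly aligned with slide in muscle alone, such a difference can also hold a slide difference. For Prune2 the muscle effect minus the cord effect was -2.39 ± 0.23, measured with another of its probes than in muscle alone, with a limma adjusted p of 0.00630. Ttbk1 had the same adjusted p, but on the main values its rise in muscle is only bounded as at least 2.90-fold, so no size is given. Bcl2a1d, which protects leukocytes from apoptosis, differed by 2.11 ± 0.22, the p53-induced Trp53i11 by 1.75 ± 0.20, and the activation marker of antigen presenting cells Cd83 by 1.84 ± 0.21, with adjusted p-values from 0.00818 to 0.0113. In limma 104 of 18734 genes passed, 72 with a higher effect in muscle and 32 with a lower one, and 3589 had an unadjusted p under 0.05. The count was not stable when 1 array was left out, which leaves a group of 2. It fell to between 3 and 13 whichever cord array was left out. Without muscle untreated replicate 1, 2 or 3 it was 614, 13 and 173. Without muscle pioglitazone replicate 1, 2 or 3 it was 5, 139 and 82. It was 4 with replicate number as a block, 295 with mouse as a random block if equal numbers are 1 mouse, which the labels do not say, 649 with slide as a random block, 164 with series matrix values, 20 without a filter on dim probes (6 of them among the 104), and 3383 with slide as a block, which in muscle rests on untreated replicate 3 alone. Extracellular matrix genes had the stronger effect in muscle, by a median of 1.49 in 21 of 21 members (camera adjusted p = 3.14e-10; adjusted p = 0.179 with an estimated correlation), and 14 of them passed adjusted over the list alone against 1 over all genes.

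The tissue comparison in untreated mice described what each tissue measures. Myh4 and Myh1, myosins of fast fibres, were at least 14455-fold and 4191-fold higher in muscle, with 1 and 2 of 3 cord arrays above background. The oxygen store Mb was higher by 10.24 ± 0.63 log2 units and the Z-disc protein Csrp3 by 9.34 ± 0.79. By their brightest probes, which no untreated muscle array measured above background, the neuronal splicing factor Rbfox3 was at least 753-fold higher in cord, and the myelin genes Mobp and Cldn11 at least 1556-fold and 1298-fold. The probes of Slc32a1, the inhibitory transmitter carrier, disagreed in size: the brightest was at least 2476-fold higher in cord, while the one above background on all arrays differed by -4.23 log2 units. These 8 genes had limma adjusted p-values from 6.42e-08 to 0.000110. Of 22700 genes 16487 passed, 10070 higher in muscle and 6417 higher in cord. The share higher in muscle was 61.1%, against 43.2% with the series matrix values, where the median over all genes moved from 0.40 to -0.10. It was 71.4% without a filter and 56.0% after quantile normalisation. Groups did not overlap for 17578 genes, 77.4%, against a rough guide of 10% by chance.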

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

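The tests on untreated replicate 3, on the muscle lists and on cord groupings with the muscle groups kept were chosen only after the result was seen, while the other regroupings of arrays and the test of muscle transcripts in cord were written before theirs. Each gene and list of this paragraph and the next was noticed because the effect of pioglitazone differed between muscle and cord in a limma test of that difference. The difference passed for 104 genes. Muscle effect minus cord effect was 2.11 for Bcl2a1d, 1.84 for Cd83, 1.77 for Cldn5, 1.75 for Trp53i11, 1.74 for Myoz3, 1.67 for Sparc, 1.41 for Ache and 1.08 for Irf5. For Igfbp2 and C1qtnf3, which 2 of 3 untreated muscle arrays measured above background, the fitted values were 2.31 and 1.89. For Ttbk1, which no untreated muscle array did, the fitted value was 3.29, a number that rests on signals under the floor. On the main values the rise of Ttbk1 in muscle is only bounded as at least 2.90-fold. The difference was -2.53 for Lgals3, -2.39 for Prune2, -1.88 for Ncam1 and -1.20 for Gstm2, where the 3 Ncam1 probes disagreed in cord, from -0.27 to 0.11, and the fit used the last. Adjusted p-values of these 15 genes lay between 0.00630 and 0.0483, and their cord effects between -0.27 and 0.41.

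Gene lists differed by camera with a median of 1.49 for extracellular matrix, 1.15 for fibroblast, 0.74 for NADPH oxidase, 0.69 for macrophage, 0.60 for PPAR target, 0.58 for classical activation, 0.55 for endothelial, 0.46 for immediate early, 0.23 for oxidative phosphorylation and 0.20 for glycolysis genes, and with -0.33 for unfolded protein response and -0.22 for ribosomal protein genes. With an estimated correlation their adjusted p-values lay between 0.179 and 0.713, and none passed.

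Regrouping the arrays asked whether chance alone gives as many calls. For the difference between tissues, 2 of 100 drawn regroupings, the real one included, gave at least the real 104 genes, and the highest other gave 237. Every other draw with over 4 genes kept the real muscle groups, however, so that count follows muscle. With the muscle groups kept, 4 of 20 groupings of the cord arrays gave as many genes, and the highest other, with both cord groups exchanged so that the effects add up, gave 1371. The 20 groupings are too few for a share under 0.05, and the count of 104 is weak evidence that cord responded otherwise than muscle. Treatment was also partly aligned with slide in muscle and not in cord. For these genes and lists, regrouping therefore cannot tell an effect of the drug from a slide difference. Within 1 tissue the 10 splits are too few for a share under 0.05. As many genes were called in 1 of 10 splits in muscle (20 in the real one, at most 1 in the others), in 10 of 10 in cord (0 in all) and in 1 of 10 for the tissues (16487, and 0 in the others). As many lists were called in 1 of 10 in muscle (17, at most 15 in the others) and in 5 of 10 in cord (8, at most 16 in the others).

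Connective tissue, macrophage and endothelial genes were higher in pioglitazone muscle, while untreated replicates 1 and 2 lay on another slide than the pioglitazone arrays. The extracellular matrix median was 1.72 within the shared slide, where slides cannot differ, but that value rests on a single untreated array that itself stood apart. It was 1.20 without that array, so the rise did not need replicate 3, but treatment and slide then coincide. Neither value separates the drug from both slide and replicate 3. A lower share of fibre RNA would raise all other cell types alike, and the medians of 4 such lists, from 0.35 to 1.22, had a permutation p of 0.0572 for their range, which settles nothing. An earlier form of this test counted fast fibre members, 16 of 16 higher (exact sign test p = 3.05e-05), and would have spoken against a lower share, but it was replaced after its outcome was seen because members share arrays and the lowest pioglitazone array, at 7.90, lay below the highest untreated one, at 7.99. An effect of the drug on these cells stays open and was not tested.

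Untreated replicate 3 stood apart in both tissues. A fault of a single hybridisation would leave the deviations of its cord and muscle arrays unrelated, yet they had r = 0.43 across genes. Other pairs of untreated arrays had at most 0.26, but deviations from a mean of 3 arrays sum to 0. Those values thus follow in part from replicate 3 and are no separate yardstick. Separate faults on both arrays were not tested. Of 5 quality measures, 2 in cord (spike-in slope, spots above background) and 3 in muscle (negative controls, replicate spread, 75th percentile) lay outside the range of the other arrays, none of them in both tissues. Whether equal numbers are 1 mouse stays open, since 4 of 36 ways to match numbers gave a sum of correlations as large (exact p = 0.111). High glucocorticoid response genes on this replicate and on pioglitazone replicate 2 could reflect the state of a mouse at sampling, a hypothesis that no value in the labels could test and that the 0.43 alone does not establish.

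Muscle fibre transcripts were present on cord arrays. If muscle was carried into the cord samples, fast fibre genes should follow a separate list of abundant muscle transcripts over the 6 arrays, and they did, with Pearson r = 0.96 (exact permutation p = 0.00694), Spearman rho = 0.943 (exact permutation p = 0.0167) and r = 0.912 without the 2 farthest arrays. Acta1 ran from -1.82 to 0.76 over the cord arrays, and Myh4 did not keep 1 ratio to it, so which muscle this came from stays open. Myh4 followed the amount of muscle signal only in part. On untreated replicates 3, 1 and 2, Acta1 was at -1.82, -1.48 and 0.76 and Myh4 rose with it, at -7.08, -6.28 and -3.13. The former 2 Myh4 values lay under the floor. Pioglitazone replicate 3, with Acta1 at 0.45, had the highest Myh4, at -0.70. Pioglitazone replicates 1 and 2 left that order: with Acta1 at -1.23 and -1.56, they had Myh4 at -1.91 and -0.93, above untreated replicate 2. Expression of these genes by cells of the cord was not tested. The r of 0.96 is of list means and does not tell why Myh4 was higher in pioglitazone cord, so that stays open.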

How the results depend on the processing

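The slide and replicate 3 alternatives for lists and within a slide were tests chosen only after the result was seen. Cord genes stayed at 0 passing under every alternative that kept all 6 arrays, and at 0 to 2 when 1 was left out. The 20 muscle genes became 47 with normexp (8 shared), 10 with quantile normalisation, 19 with median centring, 28 with probe means, 0 without a filter, 12 when above background on all arrays, 6 with trend and robust, 3479 in a shared fit, 4482 with slide as a block, 169 with slide as a random block, 0 with replicate as a block, 67 with series matrix values and 3314 within slide 2, and 0 to 263 when 1 array was left out. The 104 genes of the difference became 20 without a filter, 3383 and 649 with slide as a block and as a random block, 4 with replicate as a block, 164 with series matrix values, 295 with mouse as a random block, 100 without untreated replicate 3 of both tissues (54 shared), and 3 to 614 when 1 array was left out. Of the cord lists, 0 passed with an estimated correlation, 0 with fry and 14 with normexp, and of the muscle lists 0 and 8 with the former 2. The tissue difference stayed between 12784 and 23700. The cause was not tested, except that dropping the filter raises the number of genes tested. Leaving out an array leaves a group of 2, and the lone array within slide 2 is assumed to vary like the others. All cord arrays share 1 slide, so slide as a block was not run there. Arrays with equal numbers had r from -0.32 to 0.12 within a tissue, so numbers were not used as pairs. Signal limits what can be seen: 53.0 to 56.1% of cord spots and 47.9 to 51.9% of muscle spots were well above background.

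The following log2 values changed sign with an alternative, and the cause was not tested. With quantile normalisation this held for Gfap, spinal cord, at 0.0017 (from -0.026), Oxidative phosphorylation, spinal cord, at 0.017 (from -0.011), Glycolysis, spinal cord, at 0.026 (from -0.019), Oxidative stress response, spinal cord, at 0.00041 (from -0.042) and Ar, skeletal muscle, at 0.00078 (from -0.064). It further held for Cpt1b, skeletal muscle, at 0.0078 (from -0.082) and Fatty acid oxidation, skeletal muscle, at 0.022 (from -0.045). With median centring this held for Fabp3, spinal cord, at -0.0037 (from 0.0050). With probes above background on all arrays this held for Adipocyte markers, spinal cord, at 0.062 (from -0.034). With probe means this held for Cpt1b, spinal cord, at 0.036 (from -0.20), Gfap, spinal cord, at 0.029 (from -0.026), Satellite cell and regeneration genes, spinal cord, at -0.011 (from 0.092), Androgen receptor responsive genes, spinal cord, at 0.013 (from -0.047) and Itgam, skeletal muscle, at 0.18 (from -0.24). With series matrix values this held for Oxidative phosphorylation, spinal cord, at 0.0058 (from -0.011), Fatty acid oxidation, skeletal muscle, at 0.019 (from -0.045) and Astrocyte markers, skeletal muscle, at 0.044 (from -0.020). With normexp this held for Cholesterol and fatty acid synthesis, skeletal muscle, at -0.0071 (from 0.12) and Astrocyte markers, skeletal muscle, at 0.013 (from -0.020). With slide as a block, and alike within slide 2, this held for Pparg, skeletal muscle, at 0.51 (from -0.097), Ppargc1a, skeletal muscle, at 0.18 (from -0.26), Cpt1b, skeletal muscle, at 0.014 (from -0.082), Hmox1, skeletal muscle, at -0.20 (from 0.16) and Cat, skeletal muscle, at -0.0048 (from 0.086). It further held for Trim63, skeletal muscle, at -0.38 (from 0.33), Oxidative stress response, skeletal muscle, at -0.12 (from 0.063) and Astrocyte markers, skeletal muscle, at 1.17 (from -0.020). With slide as a random block this held for Pparg, skeletal muscle, at 0.19 (from -0.097), Hmox1, skeletal muscle, at -0.010 (from 0.16) and Trim63, skeletal muscle, at -0.00048 (from 0.33). Only within slide 2 this held for NF-kB target and inflammatory cytokine genes, skeletal muscle, at -0.11 (from 0.28) and Motor neuron markers, skeletal muscle, at -0.34 (from 0.16).

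When each array was left out in turn, these values crossed 0, and no other named result did. Ranges were Adipocyte markers, skeletal muscle, -0.20 to 1.28, Ar, skeletal muscle, -0.26 to 0.11, Astrocyte markers, skeletal muscle, -0.19 to 0.48, Cat, skeletal muscle, -0.14 to 0.20 and Cholesterol and fatty acid synthesis, skeletal muscle, -0.12 to 0.47. Further ranges were Cpt1b, skeletal muscle, -0.14 to 0.019, Fatty acid oxidation, skeletal muscle, -0.20 to 0.059, Fbxo32, skeletal muscle, -1.53 to 0.49, Hmox1, skeletal muscle, -0.21 to 0.35 and Oxidative stress response, skeletal muscle, -0.18 to 0.13. Others were Pparg, skeletal muscle, -0.40 to 0.20, Satellite cell and regeneration genes, skeletal muscle, -0.29 to 0.021, Trim63, skeletal muscle, -0.69 to 0.94, Adipocyte markers, spinal cord, -0.32 to 0.042 and Angptl4, spinal cord, -0.65 to 0.29. Ranges were Astrocyte markers, spinal cord, -0.0056 to 0.048, Blood cell markers, spinal cord, -0.72 to 0.038, Classical macrophage and microglia activation, spinal cord, -0.028 to 0.16, Endothelial markers, spinal cord, -0.069 to 0.23 and Fabp3, spinal cord, -0.070 to 0.13. Further ranges were Fabp4, spinal cord, -0.58 to 0.44, Fbxo32, spinal cord, -0.033 to 0.29, Gfap, spinal cord, -0.15 to 0.19, Glycolysis, spinal cord, -0.040 to 0.029 and Mitochondrial biogenesis, spinal cord, -0.085 to 0.0040. Others were NADPH oxidase subunits, spinal cord, -0.020 to 0.13, NF-kB target and inflammatory cytokine genes, spinal cord, -0.079 to 0.0071, Nfkb1, spinal cord, -0.10 to 0.0071, Oxidative phosphorylation, spinal cord, -0.054 to 0.035 and Oxidative stress response, spinal cord, -0.099 to 0.018. Ranges were PPAR target genes of lipid handling, spinal cord, -0.13 to 0.017, Pdk4, spinal cord, -0.66 to 0.18, Pparg, spinal cord, -0.11 to 0.075, Slow fibre genes, spinal cord, -0.13 to 0.11 and Ucp2, spinal cord, -0.36 to 0.041. Further ranges were Ucp3, spinal cord, -0.28 to 0.056.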

Other observations

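The comparisons given here were looked at only after the results were seen, and none of the values in this part comes from a planned test. Across 18734 genes the pioglitazone effects in the 2 tissues had Pearson r = 0.37 and Spearman rho = 0.31. Without untreated replicate 3 of both tissues r was 0.22, without replicate 2 it was 0.40 and without replicate 1 it was 0.39. Cdkn1a, an inhibitor of the cell cycle that glucocorticoids induce, was at 5.05 on the cord array of untreated replicate 3 and at 5.27 on its muscle array, and between 1.30 and 4.24 on all other arrays. Interferon response genes on untreated replicate 3 were at -0.55 in cord and -1.20 in muscle against the other 5 arrays of the tissue, and adipocyte markers at -2.34 in muscle. Aif1 was lowest on this replicate, at -0.64 in cord and -4.20 in muscle.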
